A study of Mus musculus with 4 samples.

How the data were processed

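Expression was measured on 4 Agilent whole mouse genome arrays in the 44k format, per the labels, with a cocaine mouse and a saline mouse in the 2 channels of each array. Aliquots of 75 ng of total RNA, extracted with a PicoPure kit, were labelled with Cy3 or Cy5 after linear amplification, per the labels' protocols. The submitters' processing notes name Agilent Feature Extraction, with no version. The deposited table holds 1 log2 ratio per spot and array for 45220 spots, with 0 missing values and 0 columns left unused. The intensities behind the ratios, the spot flags and the scanner settings were not used here.

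What the values are was worked out from the table. On array 3, 98.62% of the values were the log2 of a ratio of whole numbers within a tolerance of 2e-13, against 0.14% of the same values after a small random shift. On array 1, which has fewer decimals, the shares were 99.37% and 77.58%, which does not decide. The deposited log2 values of array 3 therefore behave as raw ratios of scanner intensities, with no background subtraction visible. Arrays 1, 2 and 4 were taken to be of the same kind, which this check does not decide. On all 4 arrays the medians lay away from 0 and the ratios kept a dye bias, so no normalization between channels was visible. Ratios without background subtraction understate the fold of dim transcripts. The scale is taken as log2 on this basis, the columns were not centred, and the direction of the ratio is only likely.

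The fit had been planned on values that the authors had normalized, read as Cy5 over Cy3, and the table met neither assumption. Arrays of opposite dye orientation correlated below 0, so the columns were read as already turned, the treatment coefficient was the mean over the 4 columns, and the dye coefficient was their mean signed by dye orientation. Each array was normalized by loess (limma's loessFit, span 0.3) on the dye bias averaged over both orientations, in which a treatment effect cancels. This step was chosen after the deposited values were seen and before any test. It removes the dye effect by construction, so that effect was fitted on the values as deposited. It also brings the means of both dye orientations close together for each gene, so the 4 array values of a gene are not independent. The fit as first planned and the fit with no normalization are among the alternatives.

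Rows equal to 0 on all 4 arrays (202, none with a symbol) were left out, which left 45018 spots. Gene symbols came from the platform annotation and were checked by Entrez identifier against a table of RefSeq genes of the assembly GRCm38.p6. Of the probes 33653 had 1 symbol, 56 had several and 11511 had none. By identifier 33517 matched, and 0 symbols changed. Probes with several symbols or none were tested as single spots and are not named. Spots of 1 gene were averaged, which gave 30452 features and 19087 genes. Among the named genes, spots of Fos, Fgfr3, Folr1, Ptprc, Ptprz1, Reln and Th disagreed in sign. No genome build was named for the array, so no coordinates are given. Spots were called above background where the averaged dye bias exceeded 0.017 on the log2 scale, 3 SDs above the mode of the dim spots. By this limit 30662 spots (68.1%) and 14618 genes were above background. This is a stand-in, as no intensities were used.

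Each feature was tested with limma 3.58.1 in R 4.3.3 (lmFit with a treatment and a dye term, then eBayes), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The moderated test had 5.21 degrees of freedom in total. The 24 gene lists fixed before the data were examined covered immediate early genes, dopamine signalling, glucocorticoid response, stress, ion channels and receptors, and markers of the neuronal, glial, vascular, meningeal and blood cells that the dissected tissue could hold. Each was tested with camera at a preset correlation of 0.01, with an estimated correlation, with ranks, and with fry. Of 6 lists that passed with the preset correlation, 0 passed with an estimated one and 0 with fry. The estimated one was 0.0066 for the oligodendrocyte list, below the preset. A call lost in this setting was therefore not always lost to a higher correlation. With an estimated correlation camera takes its degrees of freedom from the residuals. These are few with 4 arrays, a treatment term and a dye term. With the preset correlation it takes them from the number of genes. A list could therefore hardly pass with an estimated correlation, and a call lost there does not show that the list did not differ.

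The genes named follow a rule fixed before the data were examined. It takes up to 12 genes per side that passed with the same sign on 4 arrays, fills each side with genes of at least 1.5-fold and the same sign that did not pass, and adds the 2 members of each list with the smallest p. Fos, Egr1, Arc, Drd1, Drd2, Ppp1r1b, Th and Slc6a3 were fixed by name, and the dye effect has its 3 largest genes per direction. Symbols that are only clone or locus identifiers were passed over.

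The procedure was tested on simulated data for this comparison, with 30452 features, 4 arrays and independent noise drawn from the fitted variances. It recovered 34 of 50 genes changed 1.5-fold, 47 of 50 changed 2-fold, 49 of 50 changed 3-fold and 50 of 50 changed 4-fold. There were 8 false calls among 188. All these genes were changed at once, and the adjustment is stricter where fewer genes change. The shares may therefore overstate recovery from the real arrays, which also differed along lines that independent noise leaves out. The alternatives were median centring, scaling of the spread, single spots, array weights, robust eBayes, a spread filter, no dye term, other thresholds, and leaving out each array. Where an array is left out, the dye term gives the array left alone in its orientation as much weight as both others together. Such fits can therefore move more than the loss of 1 of 4 equally weighted arrays would. Added after the data were seen were no normalization, loess on an intensity recovered from the whole-number ratios, spots above background alone, and genes with 1 symbol alone. The recovered log2 intensity is the larger of those of arrays 1 and 3, whose correlation was 0.82, and rests in part on array 1, which the whole-number check does not decide. The 201 spots without a match were set to the highest value.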

Results

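Gene expression was measured in the globus pallidus of male C57BL6 mice, the inbred strain named in the labels, after a conditioned place preference protocol. In this test an animal learns to associate a compartment with a drug, and the time it later spends there gives the score. Cocaine mice received 15 mg/kg on days 2, 3 and 4 of the protocol and had a low place preference score, and saline mice received saline on those days. The globus pallidus is a nucleus of the basal ganglia whose GABAergic neurons receive input from the striatum. Each of 4 arrays of 60-mer probes set RNA of 1 cocaine mouse against RNA of 1 saline mouse, with cocaine in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4. All 4 arrays form 1 group, and their number limits the precision of every value. The labels describe the hybridizations as independent and give each channel its own animal code, so each array was taken as 1 biological replicate.

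The values deposited by the authors were log2 ratios with a strong dye bias. The deposited medians were 0.33 on array 1, -0.25 on array 2, 0.49 on array 3 and -0.56 on array 4. Between arrays of the same dye orientation the Pearson correlation across 45018 spots was 0.90 for arrays 1 and 3 and 0.87 for arrays 2 and 4. Between arrays of opposite orientation it lay between -0.83 for arrays 1 and 2 and -0.96 for arrays 3 and 4. The columns had therefore likely been turned by the authors so that every array read in the same treatment direction. Which treatment was the numerator is not settled by the values. Cocaine over saline is taken as likely here, from the order in which the study's design text names the treatments. "Higher" and "lower" below mean higher or lower in cocaine mice under that reading, and every direction of a gene or list, and every dye side, reverses if the ratio was saline over cocaine.

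**Figure D1:**
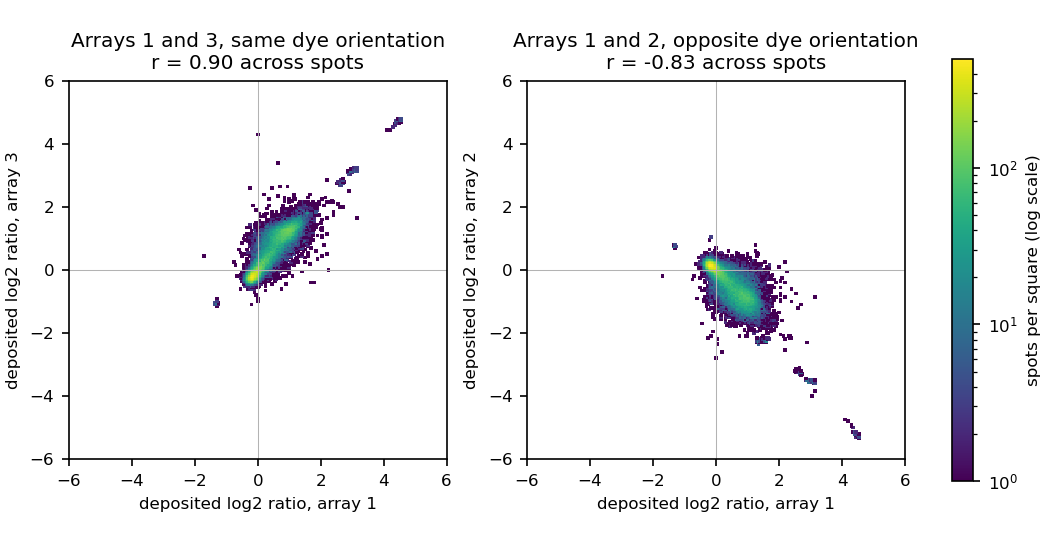
Deposited log2 ratios of array 1 (x axis) against array 3, which has the same dye orientation (left), and against array 2, which has the opposite orientation (right), with colour for the number of spots per square on a log scale. The correlation across spots was 0.90 on the left and -0.83 on the right, and the separate clusters far from the origin hold spots that followed the dye.

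The comparison asked which pallidal transcripts differed between cocaine mice with a low place preference score and saline mice. All cocaine mice on the 4 arrays had a low score, so cocaine and the low score cannot be told apart. A treatment effect below means both together. No gene passed the test. The largest difference on the higher side with the same sign on 4 of 4 arrays was that of Cxcl10, an interferon-induced chemokine, with a log2 ratio of 0.59 (SE 0.14, n = 4 arrays), which is 1.51-fold. On the lower side, Nyap1, a neuronal adaptor of phosphoinositide 3-kinase signalling, had a log2 ratio of -0.66 (SE 0.23). Mageh1, a member of the melanoma antigen family, had a log2 ratio of -0.59 (SE 0.23). These 3 genes were the only ones with 1 symbol, the same sign on 4 of 4 arrays and at least a 1.5-fold mean difference. The values were uneven across arrays: Cxcl10 stood at 0.78, 0.21, 0.40 and 0.99 on arrays 1 to 4, and Nyap1 stood at -1.09 and -1.24 on arrays 1 and 2 and at -0.22 and -0.07 on arrays 3 and 4. Mageh1 showed the same division, with -1.17 and -1.03 against -0.02 and -0.14. The loess ties the 4 array values of a gene together, so such a division does not rest on 4 independent values. Without single arrays the log2 ratio ranged from 0.38 to 0.76 for Cxcl10, from -0.87 to -0.35 for Nyap1 and from -0.91 to -0.31 for Mageh1, so each fell below 1.5-fold in at least 1 such fit. In these fits the array left alone in its dye orientation counts as much as both others together, which widens such ranges where arrays are uneven.

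With limma, 0 of 30452 features, of which 19087 were genes with 1 symbol, had an adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 529 features, 1.74% of those tested, with 244 higher and 285 lower. Chance alone would give a share of about 0.05, so this count holds no sign of a difference. It does not show that there is none. Arrays set against arrays gave more such features (1286 and 2162), and these differences between arrays enter the SE. The test of treatment is therefore strict here. Among genes these were 290, with 162 higher and 128 lower. Of these genes 277 had the same sign on 4 arrays, against 14.8% of all genes. For genes named below for a small p, the same sign on 4 of 4 arrays was therefore nearly fixed by that choice and adds little. The median SE of a gene's log2 ratio was 0.057. The count of 0 became 18 with each array centred on its median in place of loess, and 60 without the tenth of features with the smallest spread, with Cxcl10, Nyap1 and Mageh1 past the threshold under both.

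Glucocorticoid-responsive genes are here mainly transcripts that adrenal steroids induce through the glucocorticoid receptor. Their list had the smallest p of the 24 lists by camera with a preset correlation of 0.01 (adjusted p 9.18e-09). This call was lost (adjusted p = 0.594) with an estimated correlation. That setting rests on the few residual degrees of freedom, so the loss decides little. The median log2 ratio of the list was -0.13, and 18 of 20 measured members were lower. Arrdc2, an arrestin-domain gene, had a log2 ratio of -0.29 (SE 0.05, n = 4 arrays), lower on 4 of 4 arrays. Per1, a period gene of the circadian clock that glucocorticoids also induce, had a log2 ratio of -0.35 (SE 0.06), lower on 4 of 4 arrays and equal to 1.27-fold. Other members with an unadjusted p under 0.05 were Plin4, a lipid droplet protein, at -0.51 (SE 0.16), Cdkn1a, the cell cycle inhibitor p21, at -0.36 (SE 0.10), Sgk1, a kinase induced by serum and glucocorticoids, at -0.34 (SE 0.11), Map3k6 at -0.33 (SE 0.08) and Tsc22d3, known as GILZ, at -0.19 (SE 0.06). These 5 are named because they complete a count of 7 and were chosen after their values were seen. Nr3c1, the glucocorticoid receptor itself and also a member of the list, had a log2 ratio of 0.03 (SE 0.05). Fkbp5, a co-chaperone of that receptor, had -0.16 (SE 0.07). Both were also chosen after their values were seen.

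No member of this list passed over all genes, and 2, Arrdc2 and Per1, passed when adjusted over the list alone (adjusted p 0.024 for both). The list's median was -0.13, -0.01, -0.14 and -0.23 on arrays 1 to 4, and without replicate 4 the median over members was -0.06.

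**Figure D2:**
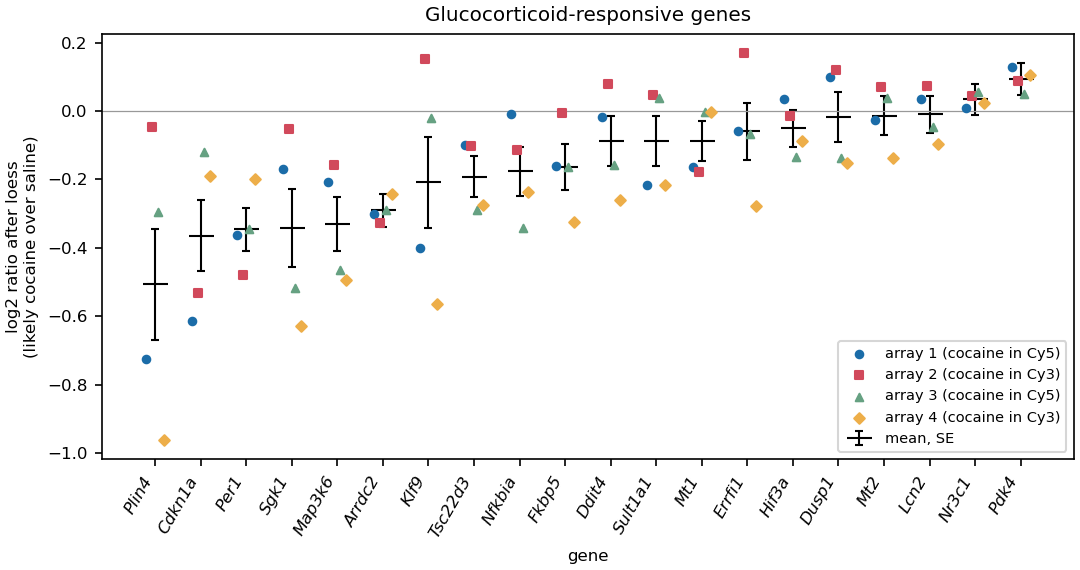
Log2 ratio after loess (y axis, likely cocaine over saline) of the 20 measured glucocorticoid-responsive genes (x axis, ordered by mean), with a coloured point for each of 4 arrays and a black bar for the mean with its SE. The means of 18 genes lie below 0, and Arrdc2 and Per1 lie below 0 on every array.

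Markers of 3 cell groups of the dissected region were also lower as lists with the preset correlation. Each of these 3 calls was lost (adjusted p = 0.594 for each list) with an estimated correlation. For the oligodendrocyte list the estimated correlation, 0.0066, was below the preset 0.01, so a higher correlation did not cost that call. The few residual degrees of freedom of that setting did. All 10 measured basal forebrain cholinergic markers, genes of the acetylcholine-releasing neurons that lie within and around the pallidum, had a mean below 0, with a median log2 ratio of -0.16. Ache, the enzyme that degrades acetylcholine, had a log2 ratio of -0.23 (SE 0.06) and was lower on 4 of 4 arrays. Slc18a3, the vesicular acetylcholine transporter, had a log2 ratio of -0.15 (SE 0.06). Of 25 oligodendrocyte and myelin markers, 18 were lower (median -0.07), with Mal at -0.11 (SE 0.05) and Mag, a myelin-associated glycoprotein, at -0.32 (SE 0.15), which ranged from -0.46 to -0.10 when single arrays were left out. Of 26 pallidal neuron markers, 21 were lower (median -0.05), with Vamp1, a synaptic vesicle protein, at -0.15 (SE 0.07) and Elfn1, a postsynaptic adhesion protein, at -0.09 (SE 0.05).

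By camera with the preset correlation the adjusted p was 1.39e-04 for the cholinergic, 4.76e-03 for the oligodendrocyte and 9.79e-03 for the pallidal list. No member of the 3 lists passed over all genes or when adjusted over the list alone. Without replicate 4 the pallidal median was 0.002 and the cholinergic median -0.05, and neither list then passed. The oligodendrocyte list did not pass without replicate 3 or without replicate 4 (medians -0.09 and -0.03).

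Immediate early genes, which neuronal activity induces within minutes, were higher as a list with the preset correlation (camera adjusted p 0.044), and not with an estimated correlation (adjusted p = 0.818). Of 33 measured members 21 were higher, with a median log2 ratio of 0.03. Fos, the transcription factor most used as an activity marker, had a log2 ratio of 0.26 (SE 0.07, n = 4 arrays) and was higher on 4 of 4 arrays. Its 11 spots ranged from -0.05 to 0.40. Egr1 had a log2 ratio of 0.30 (SE 0.22) with 0.82 and 0.75 on arrays 2 and 3 against -0.14 and -0.21 on arrays 1 and 4. Arc, an activity-regulated cytoskeletal protein, had a log2 ratio of 0.13 (SE 0.10). Per1 belongs to this list too and was its member with the smallest p, on the lower side. No member passed over all genes or when adjusted over the list alone, and the call was lost without replicate 3 (median 0.01) and without replicate 4 (median 0.05). It was also lost with no dye term, with ranks and with no normalization (adjusted p 0.112, 0.089 and 0.339).

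Markers of cortical and thalamic glutamatergic neurons, which are not neurons of the pallidum, were higher in 16 of 25 measured members, with a median log2 ratio of 0.04. The camera adjusted p was 0.0496, and adjusted p = 0.818 with an estimated correlation. Nrgn, a postsynaptic calmodulin-binding protein of forebrain neurons, had a log2 ratio of 0.24 (SE 0.07) and was higher on 4 of 4 arrays, and Slitrk6 had a log2 ratio of 0.13 (SE 0.05). No member passed over all genes or when adjusted over the list alone, and the call was lost without replicate 2 (median 0.02) and without replicate 3 (median -0.005). It was also lost with single spots, no dye term, ranks and spots above background alone (adjusted p 0.111, 0.112, 0.074 and 0.074).

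Dopamine signalling genes did not pass as a list, with 11 of 23 measured members higher (median log2 ratio -0.004). Drd1, the D1 dopamine receptor, had a log2 ratio of 0.29 (SE 0.20), with 0.89 on array 2 and -0.30 on array 4. Drd2, the D2 receptor, had a log2 ratio of -0.10 (SE 0.10), and Ppp1r1b, known as DARPP-32, -0.06 (SE 0.09). Th, which makes the dopamine precursor, had a log2 ratio of 0.02 (SE 0.05) and Slc6a3, the dopamine transporter, -0.01 (SE 0.05). Maob, a monoamine oxidase, had a log2 ratio of 0.16 (SE 0.05) and was higher on 4 of 4 arrays, and Rgs9 had 0.13 (SE 0.06). The sign of the Drd2, Ppp1r1b, Th and Slc6a3 ratios turned when single arrays were left out. None of these genes passed over all genes or when adjusted over the list alone.

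Striatal projection neuron markers, which would come from the neighbouring caudate putamen, were split evenly, with 14 of 28 measured members higher (median log2 ratio 0.001). Their medians differed between arrays, at -0.01 and -0.12 on arrays 1 and 4 and at 0.15 and 0.11 on arrays 2 and 3. Eya1, with a log2 ratio of 0.11 (SE 0.05), was the member with the smallest p. Heat shock and protein folding genes followed the same division, with medians of -0.15 and -0.16 on arrays 1 and 4 and of 0.15 and 0.11 on arrays 2 and 3. The list as a whole had a median of 0.02 over 25 members, with Herpud1 at -0.07 (SE 0.05) and Atf4, a stress-response transcription factor, at -0.17 (SE 0.12). Neither list passed the test with 4 arrays. Their estimated correlations were 0.33 (striatal) and 0.42 (heat shock), against the preset 0.01. Camera with these gave adjusted p of 0.899 and 0.963. The calls that follow are with the preset correlation. Both were called higher without replicate 1 (striatal median 0.06, adjusted p 0.019, and heat shock median 0.06, adjusted p 5.78e-04) and without replicate 4 (0.09, adjusted p 4.95e-05, and 0.11, adjusted p 2.09e-03), and lower without replicate 2 (-0.06, adjusted p 0.047, and -0.03, adjusted p 0.042).

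**Figure D3:**
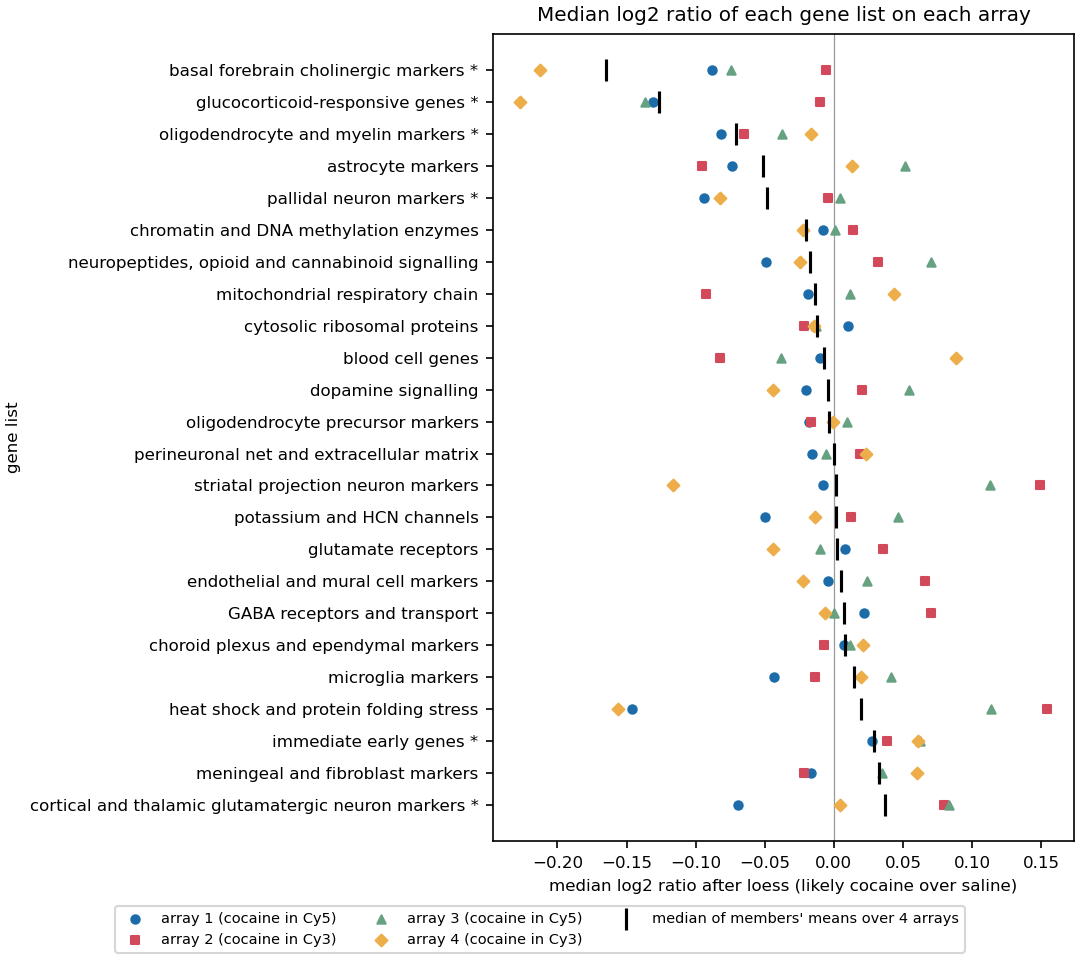
Median log2 ratio after loess (x axis, likely cocaine over saline) of the measured members of each of 24 gene lists (y axis), with a coloured point for each of 4 arrays, a black bar for the median of the members' means over 4 arrays, and a star where the camera adjusted p with a preset correlation was under 0.05. The 6 starred lists, 0 of which passed with an estimated correlation, have medians between -0.16 and 0.04, and the heat shock and striatal lists spread widest between arrays without a common shift.

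Among the other glial and vascular lists none passed. Astrocyte markers were lower in 17 of 22 measured members (median -0.05, camera adjusted p 0.065), with Sox9 at 0.15 (SE 0.06) and Fgfr3 at -0.21 (SE 0.10). This list passed with each array centred on its median (median -0.06, adjusted p 0.006), with no normalization (adjusted p 0.010) and without replicate 3 (median -0.08, adjusted p 0.009). It did not pass without replicate 1 (median -0.006) or without replicate 2 (median -0.015). With 4 arrays and an estimated correlation the camera adjusted p was 0.818. Of 21 microglia markers 12 were higher (median 0.01), with Ptprc at 0.12 (SE 0.06) and Tmem119 at -0.17 (SE 0.09). Of 28 endothelial and mural cell markers 16 were higher (median 0.005), with Abcc9 at 0.15 (SE 0.06) and Abcg2 at -0.14 (SE 0.06). Of 13 oligodendrocyte precursor markers 6 were higher (median -0.003), with Ptprz1 at 0.11 (SE 0.06) and Neu4 at -0.14 (SE 0.09). Meningeal and fibroblast markers were higher in 10 of 17 members (median 0.03). Their member Ptgds, a prostaglandin D synthase abundant in meninges and oligodendrocytes, had a log2 ratio of -0.29 (SE 0.05), lower on 4 of 4 arrays. It was the only gene outside the glucocorticoid list that passed when adjusted over the list alone (adjusted p 0.024).

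The dye effect asked how far Cy5 and Cy3 differed for the same transcript, and was fitted on the deposited values because the loess removes it. In 20178 of 30452 features it passed an adjusted p under 0.05 with limma. If the columns are cocaine over saline, Cy5 was relatively brighter in 16566 of these and dimmer in 3612. The 3612 became 125, 2156, 62 and 719 without replicates 1 to 4, and with spots above background alone 16658 features passed with 0 dimmer, which the background limit fixes because it was set on the averaged dye bias. Read as saline over cocaine, Cy5 would be dimmer in the 16566 and brighter in the 3612. The genes with the largest positive dye coefficient (Cy5 brighter if cocaine over saline, Cy3 brighter if saline over cocaine) were Lars2, a mitochondrial leucyl-tRNA synthetase, at 2.24 (SE 0.07), the ribosomal protein gene Rplp1 at 2.17 (SE 0.06) and the cytochrome oxidase subunit gene Cox6a1 at 2.11 (SE 0.07). The most negative were those of Prol1, Ifna11 and Cypt2, none of which has a spot above background, so no values are given for them. A negative dye coefficient nearly fixes this as well, because the limit was set on the averaged dye bias. With each array centred on its median the dye effect passed for 24477 features, with 11576 positive and 12901 negative, so the division between the dyes depends on the centring.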

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

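The tests of cell groups against the glucocorticoid list, and both tests of pallidal, of oligodendrocyte, and of cortical and thalamic markers, were chosen after the result was seen. Across the 56 named genes and 24 lists, 80 groups of 4 arrays were examined for a single array far from the others. Of these 0 stood out. For a gene this was nearly fixed beforehand, because the loess brings the means of both dye orientations close together. The count therefore gives no assurance that the arrays are alike.

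No gene passed the test of cocaine against saline, and 6 lists passed with a preset correlation, of which 0 passed with an estimated correlation and 0 with fry. With an estimated correlation the few residual degrees of freedom nearly fixed that outcome. The 4 arrays allow 3 balanced splits, which are too few for a share under 0.05. For genes the real split called 0 features and the highest of the others called 0, and since any split gives at least 0, the count of 3 of 3 was fixed beforehand and decides nothing. For lists the real split called 6 and the highest of the others, arrays 1 and 4 against 2 and 3, called 7 (heat shock, striatal, pallidal, cortical and thalamic, blood, neuropeptide and potassium channel lists), so 2 of 3 splits gave as many. The other splits also held more features at an unadjusted p under 0.05 (1286 and 2162 against 529) and more genes with the same sign on 4 arrays (22.3% and 24.4% against 14.8%). The arrays therefore differ from each other beyond a shift common to all 4. Each array holds a cocaine and a saline mouse, so the splits cannot tell whether these differences are unrelated to treatment.

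Glucocorticoid-responsive genes were lower on the numerator side, with a median of -0.13 (adjusted p = 0.594 with an estimated correlation). Dye bias left after normalization is not decided. The median lay at percentile 0.01, the lowest possible, among 10000 random lists matched on averaged dye bias. The loess had already removed that bias, so matched lists centre near 0 whatever moved this list. Dye bias of single probes that varies between arrays would not show in such a test. A lower share of vessel cells, which express several of these genes, is argued against as the whole cause. The endothelial and mural median minus 2 standard errors was -0.029, well above the list's median. Standard errors of a median were taken here over the genes of a list, not over arrays. On single arrays the endothelial and mural median ran from -0.02 to 0.07. A lower share of other cells stays open, since cholinergic markers were as low as the list, and the median of pallidal, oligodendrocyte and astrocyte markers lay above that of the list by less than 2 standard errors of the difference (difference minus 2 standard errors -0.253, -0.017, -0.046 and -0.025 in this order). Differences between single animals unrelated to treatment stay open, since the larger median of the 2 other splits reached 0.564 of the real one, and so does a treatment effect, untested, whose direction rests on the reading of the ratio as cocaine over saline.

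Cholinergic, pallidal and oligodendrocyte markers were lower and cortical and thalamic markers higher (adjusted p from 0.594 to 0.818 with an estimated correlation), which is the direction that a different dissection of the nucleus might give. Dye bias left after normalization is not decided for any of these lists. Their medians lay at percentiles 0.01 (cholinergic), 1.53 (pallidal), 0.08 (oligodendrocyte) and 99.8 (cortical and thalamic) of matched random lists. The loess had already removed the averaged dye bias on which those lists were matched. Dissected tissue that differed between single animals cannot be told apart from treatment for the 3 lower lists: the larger median of the other splits was 0.302 of the real one for cholinergic, 0.365 for oligodendrocyte and 0.944 for pallidal markers, with log2 standard errors of those medians (0.06, 0.03 and 0.03) that leave larger values open. For cortical and thalamic markers it was 1.51 times the real one, as such tissue differences would give. A treatment effect stays open as well, untested.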

How the results depend on the processing

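Settings added after the data were seen are no normalization, loess on recovered intensity, spots above background, and genes with 1 symbol. The count of 0 changed genes was also 0 under those 4 settings, scaling, single spots, array weights, robust eBayes, no dye term, an adjusted p under 0.1, and without each replicate (0 to 0). It was 18 (10 higher, 8 lower) with median centring, 60 (35 higher, 25 lower) without the tenth of features with the smallest spread, a filter on the same spread that enters the test, 1 at an unadjusted p under 0.01 and 1.5-fold, and 4 with the same sign on 4 arrays and 1.5-fold, 1 of them a spot without a symbol. Read as Cy5 over Cy3 with 2 arrays turned, as first planned, the deposited values gave 20178 changed features, by construction the dye effect, and 10 lists. The 6 lists were 0 with an estimated correlation, 0 with fry, 4 with ranks and from 5 to 10 without single replicates, 10 of them without replicate 1. Under that planned reading the direction of the list test, which is relative to all genes, changed for lists called in either fit, with medians for pallidal (1.11), cholinergic (0.65), cortical and thalamic (0.53), choroid plexus (-0.0056), oligodendrocyte (1.07), astrocyte (1.20), glucocorticoid (1.01), mitochondrial (1.44), ribosomal (1.28) and chromatin (0.90) lists. The cortical and thalamic median stayed above 0, and medians of precursor (0.70), dopamine (0.63), blood (0.83) and neuropeptide (0.74) lists, called in neither fit, turned. It also changed without replicate 2 for striatal (range without single replicates -0.057 to 0.091), heat shock (-0.106 to 0.107, and -0.031 without replicate 2) and mitochondrial (-0.059 to 0.072) lists. Without replicate 4 it changed for pallidal (-0.0996 to 0.0016) and ribosomal (-0.038 to 0.028) lists. The cause was not tested. The glucocorticoid list passed with the preset correlation without each replicate, with medians from -0.18 to -0.06 and adjusted p from 7.88e-14 to 0.033. The dye effect passed for 12604 to 18963 features without single replicates and for 3161 after loess on recovered intensity, which removes part of it. Mean correlation of opposite orientations went from -0.90 to -0.73, and of the same orientation from 0.89 to 0.66, in the fifth of spots with the largest spread (cause not tested). Of 56 named genes, 6 changed sign without single replicates (Arc, Atf4, Drd2, Ppp1r1b, Slc6a3 and Th), none of them a called gene, 41 moved by over 1.5 times in at least 1 such fit (all but Ache, Arrdc2, Elfn1, Eya1, Folr1, Fos, Gal, Kcnn2, Mal, Maob, Per1, Ptgds, Reln, Sox9 and Sst), and 4 passed under some alternative. A fit without a single replicate weighs the array left alone in its dye orientation as much as both others together. Values on at least 3 arrays could not differ, as none were missing. The main fit is already paired, as each log2 ratio sets 2 mice against each other on 1 array, and no unpaired fit was made. Of the spots, 68.1% stood above background, and folds of dim genes are understated where no background was subtracted.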

Other observations

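All comparisons of this part were fixed before the data were examined, and none of the lists in it passed the test of cocaine against saline with 4 arrays and the preset correlation. Neuropeptide, opioid and cannabinoid genes were higher in 11 of 27 measured members (median log2 ratio -0.02). This list was called without replicate 1 (adjusted p 0.023) and without the tenth of features with the smallest spread (adjusted p 0.018), and the test leaned higher in both. Sst, the inhibitory peptide somatostatin, had a log2 ratio of 0.22 (SE 0.06) and was higher on 4 of 4 arrays, and Gal, the peptide galanin, had -0.14 (SE 0.05) and was lower on 4 of 4 arrays. Of 17 genes of GABA receptors and transport 11 were higher (median 0.007), with Gabrd, the delta subunit of extrasynaptic receptors, at 0.28 (SE 0.12) and Slc6a11, a glial GABA transporter, at -0.14 (SE 0.07). Of 26 glutamate receptor genes 14 were higher (median 0.003), with Grin2d at 0.14 (SE 0.07) and Grin2c at -0.11 (SE 0.06). Of 65 potassium and HCN channel genes 34 were higher (median 0.002), with Kcnj4, an inward rectifier, at 0.35 (SE 0.14) and Kcnn2, a calcium-activated channel, at -0.15 (SE 0.05). Without single arrays Gabrd ranged from 0.15 to 0.40 and Kcnj4 from 0.13 to 0.55, and of the genes named in this part all but Sst, Gal, Kcnn2, Reln and Folr1 moved by over 1.5 times in at least 1 such fit.

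Among 22 genes of perineuronal nets and extracellular matrix 11 were higher (median 0.0001), with Reln, the secreted glycoprotein reelin, at 0.19 (SE 0.05), higher on 4 of 4 arrays, and Sparc at -0.12 (SE 0.05). Of 11 blood cell genes 5 were higher (median -0.01), with the alpha globin Hba-a2 at -0.30 (SE 0.10) and the neutrophil gene S100a9 at 0.40 (SE 0.15). Without single arrays Hba-a2 ranged from -0.40 to -0.14 and S100a9 from 0.20 to 0.58. S100a9 passed without the tenth of features with the smallest spread. Of 18 choroid plexus and ependymal markers 11 were higher (median 0.01), with Folr1 at 0.10 (SE 0.05) and Kl at 0.11 (SE 0.05). Of 24 chromatin and DNA methylation enzymes 8 were higher (median -0.02), with Hdac7 at -0.11 (SE 0.06) and Dnmt1, the maintenance methyltransferase, at -0.08 (SE 0.05). Of 83 respiratory chain genes 35 were higher (median -0.01), with Cox7a2l at -0.17 (SE 0.08) and Cox6a1 at 0.10 (SE 0.05). Of 75 cytosolic ribosomal protein genes 31 were higher (median -0.01), with Rplp1 at 0.12 (SE 0.05) and Rps15 at -0.26 (SE 0.11). The respiratory chain list was called lower without replicate 3 (median -0.06, adjusted p 0.009) and higher without replicate 2 (median 0.07, adjusted p 8.52e-07). These calls, and those of the ribosomal list, are with the preset correlation of 0.01. With 4 arrays the estimated correlation of the respiratory chain list was 0.15, and camera with it gave an adjusted p of 0.963. The ribosomal list was called lower without replicate 1 (median -0.02, adjusted p 0.039) and higher without replicate 4 (median 0.03, adjusted p 0.033). Cox6a1 and Rplp1 were also among the 3 genes with the largest dye effect.

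The median and the mean had opposite signs in 6 lists, those of dopamine signalling, microglia, neuropeptides, heat shock, potassium channels and perineuronal nets. For dopamine signalling and neuropeptides the test also leaned the other way from the median, and for potassium channels it leaned lower while the median was above 0.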
